A study of Mus musculus with 2 samples.

How the data were processed

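MAIT cells of mouse skin were profiled by droplet single-cell RNA sequencing at steady state and at wound day 4, with 1 library per condition. Per the labels' protocols the libraries were made with 10x Genomics 3' chemistry, version 3. Per the submitters' processing notes, reads were processed with Cell Ranger 3 and mm10, and per the file headers the matrices were written by software version 3.1.0. The deposited values are raw UMI counts per gene and cell barcode, with no normalization by the authors. How barcodes were called as cells, how MAIT cells were sorted and whether animals were pooled was not given in the sources used here. The protocol text attached to these libraries describes the isolation of goblet cells from the intestine of another mouse line and not skin MAIT cells. In the kept cells the 11 goblet and intestinal epithelial markers summed to 207 and 136 UMIs (5.91 and 3.27 CPM), against 202663 and 228822 UMIs of the 11 T cell markers.

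The matrices list 31053 genes, and of these 30934 were matched by identifier to the GENCODE annotation of the same build, from which coordinates were taken. Cells were kept with at least 500 genes, at least 1000 UMIs and under 10% mitochondrial counts. This removed 581 of 4560 steady state barcodes (12.7%) and 548 of 4933 wound barcodes (11.1%), mostly for mitochondrial counts (560 and 528). Doublets were called per library with scrublet in scanpy 1.11.5, at an expected rate of 4%. It called 1 and 2 cells, so few that the caller has not worked, and doublets must be taken as still present. The T-like cells held 34774243 and 41467807 UMIs, so that 1 UMI was worth 0.0288 and 0.0241 CPM and the floor of 3 counts 0.0863 and 0.0723 CPM.

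The cells of both libraries were clustered together without batch integration: counts were scaled to 10000 per cell and logged, 2000 variable genes were taken without T cell receptor variable and joining, sex-specific, mitochondrial and ribosomal genes, followed by 30 principal components, 15 neighbours and Leiden clustering at a resolution of 0.8. Clusters were named from fixed marker lists. The scoring rule was set after the data were seen: a marker counted as detected at 50 CPM, and the top 10 genes of a cluster were ranked by fold over the other cells with 10 CPM added to both. T-like clusters needed at least 3 detected T cell markers and fewer than 3 markers of classes outside the lymphoid ones among their top 10 genes. Of these, cycling-like and type 1-like clusters needed at least 3 of their markers among the top 10. The remaining T-like clusters were named type 17-like on at least 3 detected markers. Clusters 12 and 13, with 36 steady state cells (0.905%) and 17 wound cells (0.388%), were kept out of the T-like class by this rule.

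Raw counts of T-like cells were summed per library and divided by the library's own T-like total (CPM). With 1 library per condition no test was run between conditions. Counts were given exact Poisson intervals, folds exact conditional intervals and shares exact Clopper-Pearson intervals, all at 95% and covering counting error only. Genes with a mean of at least 20 CPM were described by a fold of at least 2. List medians used members with at least 10 CPM in 1 library, an order-statistic interval over members, which are not replicates, and a percentile among 10000 random lists of the same size drawn from 20 expression bins. Member counts use a fold of 1.5. The naming rule had 3 parts: 13 genes always named, the 10 genes with the largest fold in each direction among genes at 20 CPM whose interval excluded 1, and the 2 highest and 2 lowest members of each list. Mitochondrial, ribosomal protein, T cell receptor, haemoglobin, histone, sex-specific and unnamed model genes stayed out of the ranked part. They made up 3 of the 40 genes at least 2-fold higher, all unnamed models, and none of the 15 lower. Other genes were named after their values were seen. Some genes that the rule would name are not reported here. Shares of cells with a UMI were taken after thinning each cell to 2000 UMIs without replacement.

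The gene lists, markers, filters, scalings, naming rule and alternatives were chosen before the data were examined, except those said to be added. Alternatives covered 3 other scalings (TMM factors of edgeR 4.0.16, size factors of DESeq2 1.42.0, and totals without mitochondrial and ribosomal protein genes), the mean over cells, the cell filter, doublets, the cells summed, clustering resolutions of 0.4 and 1.2, the expression minimum and the thinning depth. edgeR and DESeq2 were used for scaling alone. Added after seeing the data were leaving out the 4% of cells with the highest scrublet scores, the 1% of cells with the most cytokine UMIs, and cluster 8. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9 and matplotlib 3.10.9, and in R 4.3.3.

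The fold calculation was tested on simulated counts for wound day 4 against steady state, drawn from the real means and totals with 200 changed genes. All 50 genes at each of 2.5-fold and 4-fold, higher and lower, passed 2-fold. Of the 5013 genes that reached 20 CPM in the simulation, 4829 were unchanged and 184 changed. Of the unchanged genes 0 passed 2-fold, and 95.4% of the intervals of the 5013 genes held the true fold. Such a simulation holds counting error alone, not differences between animals or preparations.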

Results

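Mucosal-associated invariant T (MAIT) cells are T cells with a semi-invariant receptor that recognise microbial vitamin B2 metabolites presented by MR1. Droplet single-cell RNA profiles were examined of MAIT cells from mouse skin at steady state and from skin at day 4 after wounding, in mice of the B6-MAITCAST strain. The series asks how MAIT cells help skin wounds to heal, and the comparison open to these data is wound day 4 against steady state, with 1 library per condition. The steady state library held 4560 cell barcodes with 36152837 UMIs, and the wound library 4933 barcodes with 42729491 UMIs. After filtering, 3978 and 4383 cells were kept, with a median of 8276 and 8833 UMIs per cell and 2452.5 and 2439 genes per cell. With 1 library per condition the differences have no replicate check: each describes these libraries, intervals are at the 95% level and cover counting error only, and no p-value is given.

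Nearly all kept cells carried T cell genes. T-like clusters held 3942 of 3978 steady state cells (99.1%, 98.7 to 99.4, exact Clopper-Pearson) and 4366 of 4383 wound cells (99.6%, 99.4 to 99.8). In each of the 13 T-like clusters at least 10 of the 11 T cell markers reached 50 CPM (counts per 1000000 counts). Over these clusters Zbtb16, which encodes PLZF and directs innate-like T cell development, ranged from 123 to 406 CPM, and Cd3e from 288 to 653 CPM. The other 36 steady state and 17 wound cells lay in a cluster led by collagen genes such as Col3a1, with 25 and 15 cells, and a cluster led by haemoglobin and keratin genes, with 11 and 2 cells. The collagen-led cluster also had 10 of the 11 T cell markers at 50 CPM, with Cd3e below the T-like range at 196 CPM. The marker count alone thus does not set the T-like clusters apart from it. How the cells were sorted was not given in the sources used here, and a sort can set these shares.

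Of the 13 T-like clusters, 11 were type 17-like, holding 92.2% of steady state cells (91.3 to 93.0) and 94.9% of wound cells (94.2 to 95.5). This name went to T-like clusters not named otherwise. All 13 had at least 9 of the 12 type 17 markers at 50 CPM, so these markers do not set the named clusters apart. Cluster 6 was type 1-like, with 38 and 64 cells (0.955%, 0.677 to 1.31, and 1.46%, 1.13 to 1.86), and was also led by the interferon-induced genes Ifit1, Ifit3 and Rsad2. The order of both shares turned with the clustering, to 97.6% and 97.4% type 17-like at a resolution of 1.2 and to 0.628% and 0.456% type 1-like at resolutions of 0.4 and 1.2, so no direction is read from them. Cluster 11 was cycling-like. The clusters with the most steady state cells were 0 and 1 (993 and 757), against 101 and 354 wound cells, whereas those with the most wound cells were 7 and 10 (1228 and 799), against 187 and 547 steady state cells. Cluster 9 had 23 steady state and 332 wound cells, and cluster 14 had 50 wound cells and 0 steady state cells. A cluster mostly of 1 library may be that library and not a cell type. Clusters 3, 5, 8 and 10 had 1 marker listed for another class and none of their own among their top 10 genes. Expression in the type 17-like class was therefore not compared between libraries as a unit, except as a processing alternative that summed its clusters alone. Values within clusters are given by cluster number.

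At day 4 after wounding, the T-like cells had more RNA of the type 17 cytokine genes Il22, Il17f and Il17a and of Areg, which encodes the epidermal growth factor receptor ligand amphiregulin, and less RNA of genes such as Lmna, Vim and Klrk1. Il22, whose product acts on epithelial cells, was at 18.1 CPM in the steady state library and 278 CPM in the wound library (15.3-fold, 14.2 to 16.7). Il17f and Il17a, whose products induce neutrophil-attracting chemokines and antimicrobial peptides in the epidermis, were 7.14-fold (6.53 to 7.82) and 4.02-fold higher (3.87 to 4.18). Much of this came from few cells: without the 1% of cells of each library richest in these cytokines and Ifng, Il22 was 4.58-fold and Il17f 2.84-fold higher. Areg was at 20.4 and 64.3 CPM (3.15-fold higher, 2.90 to 3.42). Lmna, which encodes the nuclear lamins A and C, was at 1181 and 449 CPM, and Vim, which encodes the intermediate filament vimentin, at 1891 and 749.8 CPM.

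Of 5068 genes with a mean of at least 20 CPM, 40 were at least 2-fold higher and 15 at least 2-fold lower in the wound library, and 96.3% differed by less than 1.5-fold. Across genes the log2(CPM + 1) values of the libraries had a Pearson r of 0.984, where genes are not independent replicates. Summing all kept cells gave 45 higher and 19 lower, and leaving out cluster 8, led by Areg, gave 41 and 16. Without an expression minimum beyond 1 count in each library the counts were 981 and 857, and at 5 CPM 89 and 36.

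The 10 genes with the highest wound to steady state ratio were Il22, Il17f, Krt83, Cxcl2, Ly6a, Il17a, Sgip1, Pak1, Serpinb9 and Plekhg1. Krt83, a hair keratin gene, was 4.64-fold higher (32.5 and 151 CPM). Its highest level in a cluster outside the T-like cells was 25.5 CPM. Cxcl2, which encodes a neutrophil-attracting chemokine, was 4.46-fold higher (68.8 and 307 CPM), and Ly6a, which encodes the surface protein Sca-1 and is induced by interferon, 4.40-fold higher (35.9 and 158 CPM). Sgip1, Pak1, which encodes a kinase downstream of Rac and Cdc42, Serpinb9, which encodes an inhibitor of granzyme B, and Plekhg1 were between 3.35-fold and 4.02-fold higher.

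The 10 genes with the lowest ratio were Myadm, L1cam, Anxa1, Klrk1, Lmna, Nkg7, Vim, Rasgef1b, Plec and Crip1. Myadm was 4.30-fold lower (62.6 and 14.6 CPM), L1cam, which encodes an adhesion molecule, 3.06-fold lower, and Anxa1, which encodes the anti-inflammatory protein annexin A1, 2.88-fold lower. Klrk1, which encodes the activating receptor NKG2D, was at 184 and 69.7 CPM and Nkg7, a cytotoxic granule gene, at 229 and 90.1 CPM. Plec, which encodes a linker of cytoskeletal filaments, was 2.16-fold lower, and Crip1 was at 2683 and 1241 CPM. Cxcl2, Ly6a, Myadm and Anxa1 were at least 5-fold higher in a cluster outside the T-like cells than in the T-like cells, as were Vegfa, Lif, Tnfrsf9, Ctla4, Ifi27l2a and Hmgcs1 among the other genes named here. Several of these genes, and Areg, are also among the top 10 genes of single clusters, so the values here are sums over all T-like cells. These were Il22, Il17f and Il17a (cluster 14), Cxcl2 (clusters 7 and 14), Areg (cluster 8) and Sgip1 (clusters 8 and 9). Others were Pak1 (cluster 9), Krt83 (cluster 4) and Myadm, L1cam and Rasgef1b (cluster 0).

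Genes that define MAIT cells differed little. Cxcr6, a chemokine receptor gene of tissue-resident T cells, was at 1295 and 1257 CPM (0.971-fold). This ratio was above 1 when the libraries were scaled by TMM factors, by DESeq2 size factors or by totals without ribosomal protein and mitochondrial genes. Zbtb16 was 1.13-fold higher (1.10 to 1.17) over all T-like cells, but higher in 3 of the 8 clusters with at least 100 cells of each library (median log2 -0.10, range -0.23 to 0.21). Trav1, the variable segment of the MAIT receptor alpha chain, which 3' libraries seldom read, was at 5.75 and 5.57 CPM, a ratio of 0.969 with an interval of 0.798 to 1.18 that held 1. Tgfb1, which encodes transforming growth factor beta 1, was 1.14-fold lower (1.11 to 1.17). Vegfa, which encodes the main blood vessel growth factor, was at 4.26 and 8.42 CPM (1.98-fold higher, 1.63 to 2.41). Tbx21, which encodes the type 1 regulator T-bet, was at 3.34 and 3.69 CPM, a difference not detectable at this depth (1.11-fold, 0.863 to 1.42).

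**Figure D1:**
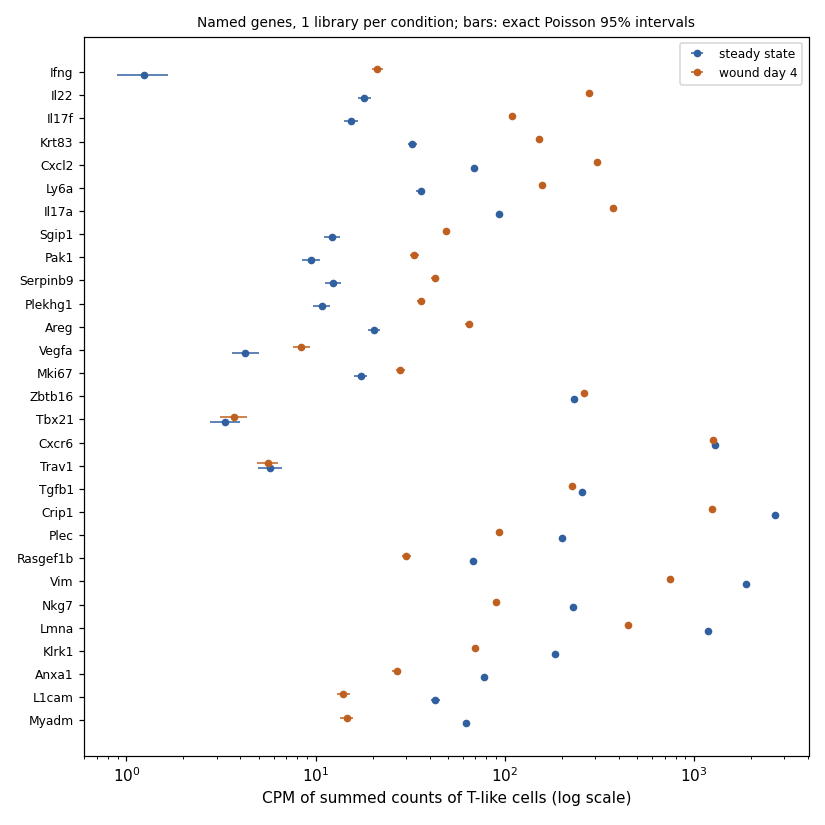
CPM (log axis) of always-named genes and of the 10 genes with the highest and the 10 with the lowest ratio in T-like cells of the steady state library (blue) and the wound day 4 library (orange), with exact Poisson 95% intervals as bars. Il22 lies at 18.1 and 278 CPM and Lmna at 1181 and 449 CPM, while the points of Cxcr6 nearly overlap.

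In mm10 coordinates of the GENCODE annotation, Il22 (ENSMUSG00000074695) spans 118204942 to 118210047 on the plus strand of chromosome 10. Il17a (ENSMUSG00000025929) spans 20730905 to 20734496 and Il17f (ENSMUSG00000041872) 20777146 to 20790617, on opposite strands of chromosome 1. Areg (ENSMUSG00000029378) spans 91139599 to 91148432 on chromosome 5, Lmna (ENSMUSG00000028063) 88480147 to 88509956 on chromosome 3 and Vim (ENSMUSG00000026728) 13573927 to 13582826 on chromosome 2. All are annotated as protein-coding, and the values count RNA over each gene as a whole.

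A small number of wound cells held much of the cytokine RNA. The 1% of T-like cells of each library with the most UMIs of Il17a, Il17f, Il22 and Ifng together (40 and 44 cells) held 54.9% of the wound library's Il17a UMIs, 71.0% of its Il17f and 81.5% of its Il22 UMIs, against 43.4%, 26.8% and 37.9% at steady state. Without those cells Il17a was still 3.21-fold, Il17f 2.84-fold and Il22 4.58-fold higher in the wound library, in counts that can include free RNA from the cells left out. The same cells, which were not chosen for Areg, held 0.225% of its wound UMIs and 11.5% of its steady state UMIs. Areg reached at least 10 UMIs in 67 wound T-like cells. Ifng, which encodes interferon gamma, was at 1.24 and 21.1 CPM, but 809 of its 877 wound UMIs (92.2%) came from 1 cell. Without that cell the log2 fold of Ifng was 0.41 (-0.16 to 0.99), and without the cell with the most Ifng UMIs of each library (10 UMIs at steady state) it was 0.79 (0.17 to 1.44), or 1.73-fold (1.12 to 2.70). Cells with at least 10 UMIs of Il22 made up 0.330% of steady state T-like cells (13 of 3942, 0.176 to 0.563) and 1.79% of wound T-like cells (78 of 4366, 1.41 to 2.22). The choice of the 1% of cells was made after the values were seen.

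**Figure D2:**
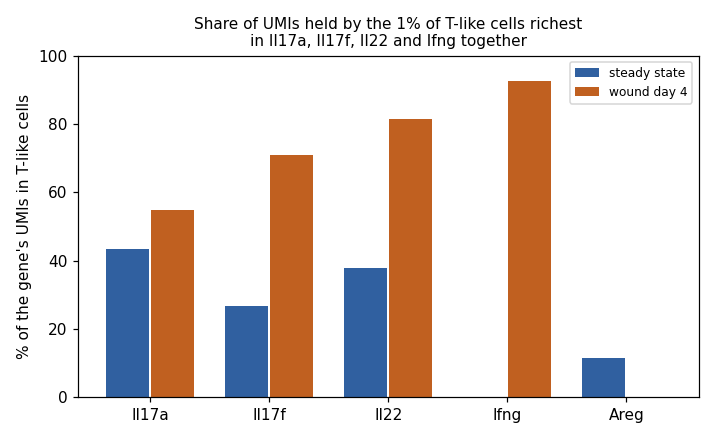
Percent of each gene's UMIs in T-like cells (vertical axis) held by the 1% of T-like cells with the most UMIs of Il17a, Il17f, Il22 and Ifng together, at steady state (blue) and wound day 4 (orange). The wound bars of Il17f, Il22 and Ifng stand at 71.0%, 81.5% and 92.6%, and the wound share of Areg, for which the cells were not chosen, is 0.225%.

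The differences were also taken cluster by cluster, in the 8 clusters with at least 100 cells of each library (0, 1, 4, 5, 7, 8, 10 and 11). Il22 was higher in the wound cells of all 8, from 0.89 to 4.96 log2, and Il17a in 7, with cluster 4 at -0.35. Lmna, Vim, Klrk1, Crip1 and Plec were lower in all 8. Areg was higher in 4: it was at 106 and 529.7 CPM in cluster 8, which Areg itself leads, and also higher in clusters 1, 7 and 11. Areg was lower in clusters 4 and 5, with log2 folds of -1.13 and -2.53, in cluster 10 it had 7 and 8 counts, and in cluster 0 it had 48 counts at steady state and 0 in the wound library. Leaving out cluster 8, the log2 fold of Areg over all other T-like cells was 1.57. That sum includes cluster 9, with 23 steady state and 332 wound cells and Areg at 102 CPM over both libraries. It can therefore follow the mix of clusters. Ifng was too rare for such a comparison, with 18 and 26 counts in cluster 5 (log2 -0.45, -1.37 to 0.50) and at most 6 counts per library in the other 7 clusters.

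Cells with at least 1 UMI were counted after thinning each cell to 2000 UMIs, which left out 15 cells of each library. Il17a was detected in 6.93% of steady state T-like cells (6.15 to 7.77) and 13.0% of wound T-like cells (12 to 14), Il22 in 1.48% (1.12 to 1.91) and 4.30% (3.71 to 4.94), Il17f in 1.73% and 3.22%, and Areg in 1.63% (1.26 to 2.08) and 2.83% (2.35 to 3.36). Unthinned, the shares were 12.5% and 22.9% for Il17a, 4.13% and 9.21% for Il22, and 3.30% and 4.99% for Areg. Zbtb16 was detected in 35.3% and 38.04%, Cxcr6 in 84.6% and 84.3% and Tgfb1 in 38.8% and 34.6% of cells. Vegfa was detected in 1.12% and 1.47%, Tbx21 in 0.688% and 0.942%, Mki67 in 1.96% and 1.86%, Trav1 in 0.993% and 1.06%, and Ifng in 0.178% and 0.230%. For Mki67 no order is read, since its CPM goes the other way.

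The shares were also set beside those in the 45 cells outside the T-like clusters that reached 2000 UMIs. All 53 cells outside these clusters had a median of 5280 UMIs per cell before thinning, against 8291.5 and 8839.5 in the T-like cells. They were not free of T cell RNA: Cd3e was detected in 16 of the 45 (35.6%), against 64.6% of steady state and 61.3% of wound T-like cells. Their shares are thus a level for comparison and not a clean background. Il17a, Il22, Ifng, Tbx21 and Trav1 were detected in 0 of 45, which allows a share of up to 6.67% by 3 counts and 7.87% by the exact interval. Of these genes Il17a alone exceeded both limits, in the wound library alone, since the interval of its steady state share held the first. Il17f and Vegfa were detected in 2.22% of these cells, Zbtb16 in 4.44% and Cxcr6 in 15.6%. Areg was detected in 17.8%, Mki67 in 6.67% and Tgfb1 in 24.4%. For Il17f this was 1 of 45 cells, with an upper limit of 11.8%, so neither of its shares can be set above or below that level. At least 10 UMIs of Il17f were held by 14 of 3942 steady state and 61 of 4366 wound T-like cells. The shares of Areg, Vegfa and Mki67 lay below those in these cells. Stromal and epithelial cells can express these genes and Tgfb1 themselves, so no class here gave such a level for them.

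Interferon-induced genes were higher as a group in the wound library. All 19 measured members of the interferon response list lay above 0, with a median log2 fold of 0.54 (0.30 to 0.65 over members) and above all of 10000 random lists matched on expression (percentile 100). Of these, 8 were at least 1.5-fold higher, and Ly6a, Ifi27l2a (35.3 and 103 CPM), Ifit1 (6.499 and 12.6 CPM) and Xaf1 (9.66 and 18.4 CPM) were the highest. Isg15, a ubiquitin-like protein gene, was higher by less than 1.5-fold, at 55.7 and 79.7 CPM. Ly6a and Ifi27l2a were also at least 5-fold higher in a cluster outside the T-like cells. Within the T-like cells the macrophage or monocyte-like markers summed to 430.5 and 644 CPM, nearly all of it Ccr2 (376 and 552 CPM) and Ctss (49.0 and 88.2 CPM), which T cells can express, while Lyz2 was at 0.460 and 0.362 CPM and Cd68 at 2.13 and 1.42 CPM. The NK or ILC-like markers summed to 168 and 205 CPM, nearly all of it Gata3 and Areg. Over all alternatives the median lay between 0.42 and 0.62.

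In the type 17 programme the cytokine genes stood apart from the rest. Of 18 measured members, Il22, Il17f and Il17a were at least 1.5-fold higher and the other 15 differed by less (median log2 0.07, -0.07 to 0.28, percentile 97.5). Ccr6, a skin-homing chemokine receptor gene, was at 116 and 93.3 CPM and the transcription factor gene Maf at 629 and 591 CPM. The type 1 and cytotoxic programme went both ways, with 6 of 8 measured members higher and 2 lower: Ifng and Ccl5 (5.92 and 18.7 CPM) were at least 1.5-fold higher, Klrk1 and Nkg7 at least 1.5-fold lower, and Gzmb, which encodes granzyme B, was at 97.8 and 146 CPM (median 0.45, -1.40 to 4.10, percentile 100). Without 1 wound cell Ifng was at a log2 fold of 0.41 (-0.16 to 0.99), and cluster 6, of 38 and 64 cells, held 162 of the 206 steady state and 689 of the 774 wound counts of Ccl5. Of the type 2 list 3 members were measured (median 0.40, with a range of -0.07 to 0.63): Csf2, which encodes GM-CSF, was at 39.3 and 60.7 CPM, Il17rb at 30.2 and 40.0 CPM and Gata3, the type 2 regulator, at 139 and 133 CPM.

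Tissue repair factors had no common direction. Of 15 measured members, 4 were at least 1.5-fold higher and 3 at least 1.5-fold lower, with a median log2 fold of 0.01 (-0.29 to 0.59, percentile 81.9). Areg and Lif, which encodes leukaemia inhibitory factor (8.45 and 24.8 CPM), were the highest, followed by Csf2 and Hbegf, an epidermal growth factor receptor ligand gene (15.01 and 22.7 CPM). Anxa1, Lgals1, which encodes galectin 1 (2689.9 and 1408 CPM), and Pdgfb (29.4 and 18.7 CPM) were the lowest. Markers of fibroblasts, another source of such factors in skin, summed to 1.78 and 1.69 CPM within the T-like cells, and the macrophage or monocyte-like markers to 430.5 and 644 CPM, with Lyz2 at 0.460 and 0.362 CPM.

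Receptors that restrain or co-stimulate T cells were mixed. In the checkpoint and co-stimulation list 4 of 12 were at least 1.5-fold higher and none that much lower (median 0.39, -0.16 to 0.94, percentile 100): Tnfrsf9, which encodes 4-1BB (21.7 and 71.6 CPM), Ctla4 (17.6 and 54.1 CPM), Pdcd1, which encodes PD-1 (79.0 and 152 CPM), and Nt5e, which encodes CD73 (81.6 and 147 CPM). By cluster, Ctla4 was higher in all 8 clusters with at least 100 cells of each library and Tnfrsf9 in 4, from -1.76 to 2.44 log2. Tox (62.6 and 48.1 CPM) and Cd28 (184 and 158 CPM) were the lowest. The T cell receptor and NF-kB activation list had 2 of 21 members at least 1.5-fold higher, Tnfrsf9 and Bhlhe40 (154 and 231 CPM), and none that much lower (median 0.08, -0.25 to 0.29). Tnf (112 and 79.7 CPM) and Il2 (10.8 and 8.01 CPM) were its lowest. Among 19 cytokine receptors 1 was at least 1.5-fold higher, Il21r at 28.0 and 43.05 CPM (median 0.11, -0.07 to 0.24). Il2ra, the high-affinity interleukin 2 receptor chain gene, was at 236 and 338 CPM, Tgfbr1 at 16.97 and 11.99 CPM and Il17ra at 51.2 and 41.3 CPM.

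Genes of migration and residency were divided. Among chemokine receptors and adhesion molecules 2 of 20 were at least 1.5-fold higher, among them Ccr7 (36.7 and 69.7 CPM), and 1 as much lower, the hyaluronan receptor gene Cd44 at 512 and 336 CPM (median -0.06, -0.29 to 0.33), while Gpr183 was at 558 and 398 CPM. The tissue residency list had a median of 0.07 (-0.33 to 0.57), with Bhlhe40 and Crem (271 and 405 CPM) the highest of 13 and Nr4a1 (849 and 650.2 CPM) and Cd69 (322 and 251 CPM), a retention factor gene, the lowest. The recirculation and quiescence list had a median of -0.06 (-0.35 to 0.77), with Lef1 (10.5 and 20.7 CPM), Ccr7 and Satb1 (482 and 823 CPM) at least 1.5-fold higher among 14 members and Txnip and Bach2 the lowest. By cluster, Lef1 was higher in 4 and Ccr7 in 5 of the 8. In the T cell receptor and MAIT identity list all 15 members differed by less than 1.5-fold (median -0.04, -0.12 to 0.10). Zbtb16 and Cd8b1 (12.1 and 13.9 CPM) were its highest members, and Thy1 (826 and 665 CPM) and Ptprc (603 and 486 CPM), which encodes CD45, its lowest.

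Metabolic lists held members that differed in both directions. Of the 15 measured members of the lipid list 10 lay below 0 and 5 above, with a median of -0.22 (-0.33 to 0.22, percentile 0.73). By their counting intervals 8 were lower and 4 higher, and the intervals of 3 held 0. The sterol regulator gene Srebf2 (90.6 and 61.0 CPM) and the cholesterol synthesis gene Hmgcs1 (33.1 and 22.5 CPM) were the lowest, while Dgat1, which encodes an enzyme of triglyceride synthesis (272 and 547 CPM), and Plin2, a lipid droplet coat gene (89.6 and 152 CPM), were at least 1.5-fold higher. In glycolysis and hypoxia 20 of 22 members differed by less than 1.5-fold (median 0.05, -0.10 to 0.16). The lactate exporter gene Slc16a3 was at least 1.5-fold higher (19.9 and 30.8 CPM) and Pfkfb3 as much lower (15.01 and 9.81 CPM), while Tpi1 was at 76.5 and 103 CPM and Slc2a3 at 23.8 and 18.1 CPM. All 28 genes of oxidative phosphorylation differed by less than 1.5-fold (median 0.01, -0.02 to 0.07), from Uqcrh (586 and 697 CPM) and Cox7c to Uqcrq and Atp5b (459 and 409.5 CPM).

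Immediate early and heat shock genes, which cell isolation can induce, had a median log2 fold of -0.06 (-0.30 to 0.04), with 21 of 23 within 1.5-fold. Klf6 (569 and 352 CPM) and Jund (3109.7 and 2051 CPM) were at least 1.5-fold lower, Jun was at 628 and 837 CPM and Hspa1b at 1078 and 1249 CPM. Signs of RNA content differed too: the median share of ribosomal protein counts per cell was 23.1% and 26.5%, and that of mitochondrial counts 5.05% and 4.98%. The ribosomal RNA related gene models Gm42418 and AY036118 were at 5661 and 4588 CPM and at 1055 and 619 CPM.

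**Figure D3:**
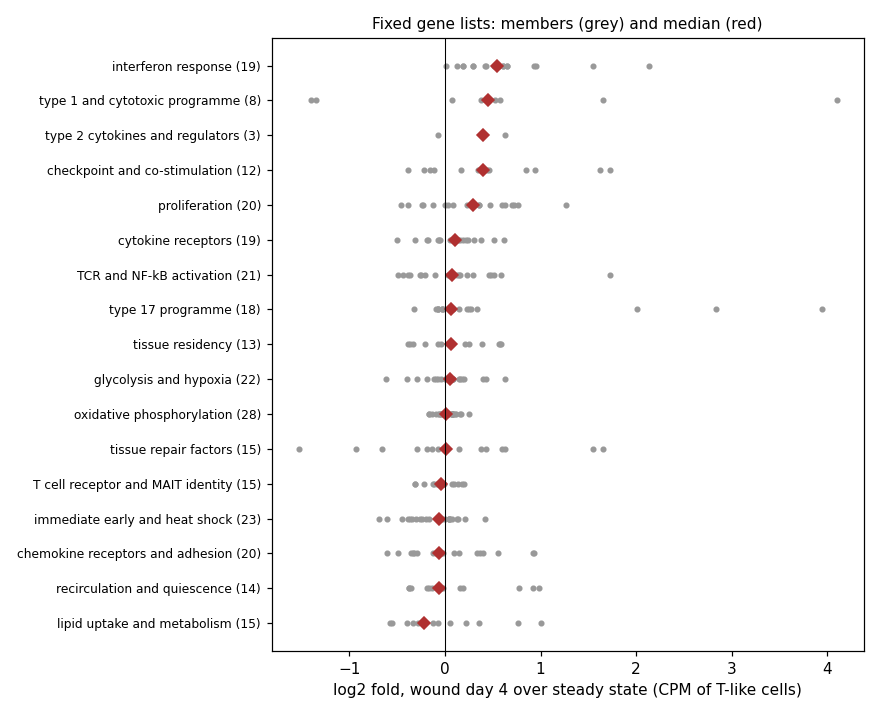
Log2 fold, wound day 4 over steady state, of the members (grey points) of the 17 gene lists in T-like cells and their median (red), with the number of measured members in brackets. The interferon response median lies at 0.54 with all 19 points above 0, and the lipid median at -0.22.

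Proliferation genes were higher in the wound library as sums over all T-like cells. Of 20 measured members 6 were at least 1.5-fold higher and none as much lower (median 0.30, 0.01 to 0.59, percentile 100). Birc5, which encodes survivin, was at 5.64 and 13.5 CPM, Rrm2, a ribonucleotide reductase gene, at 7.48 and 12.7 CPM and Mki67, the Ki-67 gene, at 17.3 and 28.1 CPM (1.62-fold, 1.47 to 1.79), while the tubulin genes Tuba1b (109 and 79.6 CPM) and Tubb5 (296 and 227 CPM) were lower. Without the cycling-like cluster the median was -0.16 and Mki67 was at -0.41 log2. That cluster was named for members of this list, among them Mki67, Birc5 and Rrm2. Leaving it out removes their counts by construction, so these values do not show where the difference came from.

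The share of cycling cells depended on how they were counted. The cycling-like cluster held 237 of 3942 steady state T-like cells (6.01%, 5.29 to 6.80) and 144 of 4366 wound T-like cells (3.30%, 2.79 to 3.87). Resolutions of 0.4 and 1.2 and keeping doublets each reversed this order, with 1.88% and 2.59% at 0.4. By UMIs of at least 3 cycling markers after thinning to 2000 UMIs, the shares were 0.866% (34 of 3927, 0.600 to 1.21) and 1.82% (79 of 4351, 1.44 to 2.26), and unthinned 2.21% and 3.30%. By at least 1 marker they were in the order of the cluster, at 9.45% (8.55 to 10.4) and 8.78% (7.96 to 9.66) thinned and 27.3% and 24.5% unthinned, and by at least 2 markers 1.60% and 2.41% thinned and 6.32% in both unthinned. Within the cluster, 58 of 237 steady state and 104 of 144 wound cells had UMIs of at least 3 markers, and its median depth was 11871 and 16648.5 UMIs per cell.

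Type 1-like cells were also taken apart. In their cluster, of 38 and 64 cells, Il17a and Il22 had 0 counts at steady state and 23 each in the wound library, Ifng was at 44.2 and 57.2 CPM (14 and 32 counts), Areg had 7 and 2 counts, and Ly6a at 123 and 529 CPM. Lmna was at 787 and 180.5 CPM and Vim at 2219 and 789.7 CPM there.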

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

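No test of an explanation was made for the values in this part. They stand here because a signal appeared in cells outside the main comparison. In the kept cells outside the T-like clusters, erythroid markers such as Hbb-bs summed to 9377 UMIs in the steady state library. Over all kept cells erythroid markers summed to 9414 UMIs at steady state and 82 in the wound library. Fibroblast-like markers such as Col3a1 summed to 2761 UMIs outside the T-like clusters at steady state and to 7313 in the wound library, in 36 and 17 cells. Within the T-like cells the same fibroblast-like markers had 62 and 70 UMIs.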

How the results depend on the processing

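The alternatives that left out cells with the highest scrublet scores, the cytokine-high cells or cluster 8 were chosen after the result was seen. Of the 83 named genes 75 kept the sign of their log2 fold under all alternatives; among the others Cxcr6 changed sign under the 3 other scalings, Trav1 under 5 alternatives, and Tbx21, Gata3 and Hspa1b under the strict cell filter of 1000 genes, 2000 UMIs and 5% mitochondrial counts. In size, 251 of the named genes' folds under alternatives left their counting interval and 1063 stayed within it, with ranges of 2.20 to 4.95 for Il22, 1.505 to 3.12 for Il17f, 1.68 to 2.40 for Il17a, 0.11 to 1.80 for Birc5, 0.88 to 2.03 for Ccl5 and 0.34 to 5.26 for Ifng. Without the cycling-like cluster Mki67 was at -0.41 and Rrm2 at -0.18 log2, and with type 17-like clusters alone at -0.38 and -0.24. Both settings leave out the cluster that was named for these genes and held most of their counts. The proliferation median was -0.16 and -0.18 under the same settings. Of the 306 list medians under alternatives 301 stayed within the interval of the reported median, but 19, in 9 of the 17 lists, had the opposite sign, among them 5 of 18 for tissue repair factors and 3 of 18 for T cell receptor and MAIT identity. Oxidative phosphorylation moved to 0.0741 with TMM factors, 0.0780 with totals without mitochondrial and ribosomal protein genes and -0.0204 with the mean over cells. Of genes at least 2-fold higher there were 89 at 5 CPM, 19 at 50 CPM and 981 with no minimum, and of genes at least 2-fold lower 36 at 5 CPM and 857 with no minimum, since the minimum sets how many genes are considered; in the other alternatives both counts stayed within 1.5 times. The higher genes were 72.7% of those past 2-fold, and 82.1%, 81.8% and 81.7% under the 3 other scalings. The T-like share was 86.0% at steady state and 84.7% in the wound library with the strict filter, under which a cluster lost its name, and 97.0% and 96.7% with no filter. The type 17-like share was 96.5% and 96.6% at resolution 0.4, 97.6% and 97.4% at resolution 1.2, 96.6% and 96.5% with genes centred per library, 96.7% and 96.7% with doublets kept, 81.1% and 74.2% with the strict filter, and 95.1% and 93.5% with no filter. The type 1-like share was 0.628% at steady state at both resolutions and with centring, 0.603% with doublets kept and 1.52% with the strict filter, against 0.456% at both resolutions, 0.433%, 0.365% and 6.24% in the wound library. The cycling-like share of kept cells was 1.86% and 2.58% at resolution 0.4, 0.754% and 1.80% at resolution 1.2, 1.78% and 2.65% with centring, 1.73% and 2.55% with doublets kept, 3.40% and 4.19% with the strict filter, and 1.14% and 2.07% with no filter. Among T-like cells it was 1.88% and 2.59% at resolution 0.4, 0.762% and 1.81% at resolution 1.2, 1.75% and 2.56% with doublets kept, and 0.866% and 1.82% by at least 3 markers at 2000 UMIs. The difference, wound minus steady state, was then 0.71, 1.05, 0.81 and 0.95 percentage points, opposite to that of the reported clustering. Except where stated, the cause was not tested. Shares of cells with a UMI moved with depth by construction, in 75 of 78 cases.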

Other observations

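Gene families outside the lists also differed between the libraries, and the families were picked after their values were seen. The GTPases of immunity-associated proteins, encoded by the Gimap genes and known for T cell survival, were higher in the wound library in 6 of 6 members at 20 CPM, with a median log2 fold of 1.47 (range 0.87 to 1.73), under every scaling tried. Gimap6 was at 41.2 and 129 CPM and Gimap5 at 15.8 and 52.4 CPM. The S100 calcium-binding protein genes were lower in 5 of 5 members (median -0.76), with S100a6 at 4991 and 2790.4 CPM and S100a4 at 3804 and 2242 CPM. Ribosomal protein genes were higher in 83 of 88 (median 0.19), and in 85 of 88 under the 3 other scalings. Hilpda, a lipid droplet gene induced by hypoxia, was at 146 and 332 CPM.

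The tests in this part were chosen after the result was seen, apart from those of the Gimap locus and of the mix of clusters. Il17a, Il17f, Il22 and Ifng were higher in the wound library. A few cells with very high counts were not the whole cause for Il17a, whose log2 fold without the 1% of cells was 1.68 (1.61 to 1.76). The ratio of Il17f to Il17a in those cells was 2.00 times that in the other wound cells (1.87 to 2.15). This ratio cannot decide on free RNA, since its interval takes UMIs as independent and 1 cell held 770 of the 4538 wound Il17f UMIs. At least 10 UMIs were held by 237 wound T-like cells for Il17a, 61 for Il17f and 78 for Il22, against the 44 cells left out. Some of the other wound cells thus held at least 10, which argues against evenly spread free RNA as the source of all RNA of these genes there. Free RNA as the source of part of it, and of all Ifng in those cells, stays open. For Ifng 1 cell held most of the wound counts, but whether it is the whole cause stays open: without it the log2 fold was 0.41 (-0.16 to 0.99), and without the highest cell of each library 0.79 (0.17 to 1.44). Doublets cannot be told apart from strong producers, since the median UMI count of the 44 high wound cells was 1.31 times that of the others, between the bounds set. Against the other wound cells these cells had a log2 ratio of -0.49 for Zbtb16 and -0.37 for Cd3e. The T cell receptor gene Trac was not lower, at 0.18 (-0.13 to 0.47), and Ctla4 and Gzmb were higher, at 2.98 and 2.59. A wound response of producing cells stays open and untested.

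Among genes of the cytoskeleton, annexins, galectins and S100 proteins, 12 picked because they were lower in the wound library had a median log2 fold of -1.03, among them Lmna, Vim, Ahnak (1051 and 518 CPM), Iqgap1 (489 and 263 CPM) and Tuba1a (90.6 and 44.2 CPM), whereas the galectin gene Lgals3 was higher (3295 and 4275 CPM). The larger share of ribosomal protein counts does not account for these 12, as their median was -0.96 (-1.27 to -0.83) with totals that left out ribosomal protein and mitochondrial genes. A difference between the library preparations cannot be told apart from the wound, because each condition has 1 library, and an effect of the wound stays open and untested.

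For the higher Gimap genes, on chromosome 6 (48647234 to 48770851), the labels give both libraries the same strain, and the 12 other measured genes within 2 Mb had a median log2 fold of 0.0183 (-0.20 to 0.08), within the 0.25 of 0 set beforehand. This argues against a strain difference that raises the genes across the locus together. A strain difference that moves single genes either way, or a variant of the Gimap genes alone, was not tested. More recirculating T cells may account for them, but the recirculation and quiescence list went both ways (median -0.0619, -0.35 to 0.77) and so decides nothing. Whether a different mix of clusters accounts for part cannot be decided: the median over 8 clusters was 0.70, against 1.47 over all T-like cells. Gimap genes are among the top 10 genes of clusters 5 and 7, so a comparison within clusters can shrink their difference by construction. Single clusters ranged from 0.25 to 0.92. The median over clusters stayed above the bound set for it beforehand, which argues against the mix as the whole cause, although the lowest cluster lay under that bound.

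Whether Areg and Il17a mark different cells was asked of the wound library at 2000 UMIs. Of 4351 cells, 123 had Areg, 565 had Il17a and 28 had both, against 16.0 if independent, a ratio of 1.75 (1.16 to 2.53). This argues against wholly separate cells, although doublets can also raise such a ratio. It also pools clusters that differ in Areg, with 290 CPM in cluster 8 and 1.30 in cluster 10 over both libraries. In the 44 wound cells with the most cytokine UMIs, Areg was at 10.8 CPM against 65.1 in the other wound cells (log2 -2.59, -4.04 to -1.46). No direction is read from this, since the interval takes UMIs as independent. At least 10 Areg UMIs were held by only 67 of 4366 wound T-like cells, so 44 cells can lack such cells by chance.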
